A study of Mus musculus with 28 samples.

How the data were processed

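The series measured chromatin by ChIP-seq in mouse embryonic fibroblasts (MEFs), primary cells of strain 129s2 grown from embryos and used at passages 3 to 4. Per the labels' protocols, chromatin crosslinked with formaldehyde was precipitated with antibodies against SIRT7 (a nuclear NAD-dependent deacylase of the sirtuin family), macroH2A1.1 (a histone H2A variant, mH2A1 in the sample names) or H3K27me3 (the histone mark laid down by Polycomb repressive complex 2). SIRT7 was precipitated from nuclear extracts and the other targets from whole cell extracts. Cells were wild type (WT) or SirT7-/- (KO), and treatment is given as NT or GS. The labels do not expand either abbreviation, and the series title concerns the response to glucose starvation. Of the 28 libraries, 20 were ChIP and 8 were input. H3K27me3 and mH2A1 had 8 libraries each, 2 per genotype and treatment, with 1 paired-end input library per genotype and treatment. SIRT7 had 4 libraries, all from WT cells and 2 per treatment, with 2 single-end input libraries per treatment.

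The submitters' processing notes name FastQC 0.11.3, Trimmomatic 0.36, Bowtie, SAMtools 0.1.19, MACS 1.4.2 and deepTools 2.4.2, and the genome builds mm9 and hg19, without saying what each was used for. Chromosome ends in the segmentations equalled the mm9 lengths rounded down to 200 bp, and all coordinates here are mm9, counted from 1. The SIRT7 peak lists are 1 per treatment, tied by the labels to both replicates and their inputs, so 1 list stands for both replicates, and whether peaks were called on pooled reads or merged afterwards is not given in the sources used here. Each peak carries a score that the authors deposited with it, a whole number from 537 to 1000 in the GS list and from 538 to 1000 in the NT list, capped at 1000. How the score was computed is not given in the sources used here, and the score served only to rank and filter peaks within a list. Both lists carry the same tag in their names, gIDR with a number. It may name a cutoff on agreement between replicates (irreproducible discovery rate), but the labels do not explain it. The chromatin segmentations are 1 per genotype and treatment, tied by the labels to the H3K27me3 and mH2A1 libraries of both replicates. Each assigns every 200 bp bin of 22 chromosomes (1 to 19, X, Y and M, 2655 Mb) to 1 of 4 states, U1 to U4. The segmentation tool, its model and the meaning of each state are not given in the sources used here. Nor is it given whether each state was defined alike in all 4 segmentations. States were therefore reported by name, and U2, U3 and U4 together were called marked sequence. The unassembled initial 3 Mb of the autosomes and of chromosome X, which can hold no reads, were U1 in all but 2 of 300000 bins in both KO segmentations and in all bins in WT, so U1 includes sequence without signal. Signal tracks named in the labels were not analysed here.

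Read totals were not given in the sources used here, so the depth behind each list and segmentation is unknown. Because replicates had been pooled, no value has a replicate error, and shares of the genome are given with their SD over chromosomes, which describes spread along the genome only. Wilson 95% confidence intervals of shares of peaks cover counting error only. All tests below compare the deposited lists and segmentations with random placements, or groups of listed peaks with one another, and do not measure variation between cultures. Segmentation shares of the genome were compared between conditions without a test.

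Overlap between the SIRT7 lists required 1 bp and was tested one-sided by moving all NT peaks of a chromosome by 1 random circular offset, 10000 times, for which the smallest possible p is 0.0001. Each peak took the state covering most of its bases, and the share of peaks in each state, and the share whose state differed between NT and GS, were compared with 10000 circular shifts of the peaks, two-sided, for which the smallest possible p is 0.0002. Peak numbers per chromosome were compared with 10000 random assignments of the peaks in proportion to segmented length. Median peak lengths were compared by permutation, and overlap on X and on autosomes by Fisher's exact test. These tests and that of peak numbers per chromosome treat peaks as independent, which clustered peaks are not. Benjamini-Hochberg adjustment was applied over the 32 state tests, the 6 state change tests, the 21 chromosomes of each list and the 4 length comparisons, with 0.05 as the threshold. Marked sequence within 100 kb of peak midpoints was summed in steps of 5 kb and compared with 1000 circular shifts. To hold the state of the peaks fixed, the share marked 50 to 100 kb away and the distance to marked sequence were also compared between peaks in U1 and shifted peaks in U1, and state change with shifted peaks weighted to the NT states of the listed peaks, adjusted over its own 6 tests. The number of GS peaks in U3 in KO-NT minus that in WT-NT was compared with 10000 circular shifts, on autosomes and on X apart. Nearness of NT to GS peaks on X was compared with 10000 circular shifts of the NT peaks. The matched, difference and nearness tests were chosen after the other results were seen. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

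The procedures were tested on simulated lists of known content. With randomly placed lists of 90 and of 2671 peaks, 3.44% of state tests over both sizes had a permutation p under 0.05. A list depleted from marked sequence gave a U1 ratio of 1.16 against a true 1.17, a list of 90 peaks with 30.0% planted overlap gave 30.0%, and a planted excess on X of 1.88 was recovered as 1.88. Of 20 lists with a preference for U1 at the peak alone, 0 gave a permutation p under 0.05 in the matched test of marked sequence in WT-NT or in that of state change in WT, and the other segmentations, KO and WT minus KO were not simulated.

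Regions named in the text follow a rule fixed before the data were examined: the 10 peaks of each list with the highest score (ties by length), the 1 Mb window with the largest gain and the largest loss of each state in each genotype, chromosomes X and Y, and any chromosome whose peak density passed the test. Other named regions were chosen after their values were seen. No gene annotation of build mm9 was used here, so peaks and windows are given by position only. The planned comparisons of peaks with promoters, exons and introns, and of chromatin states at promoters of 17 fixed gene lists, were not run. For the same reason the state of the deleted SirT7 gene, which could check the genotype labels, was not examined. Alternatives were other overlap rules, random placements, score filters, chromosome sets, bin sizes and treatments of short segments. Leaving out a replicate was not possible with pooled files.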

Results

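The data comprised 2 lists of SIRT7 ChIP peaks in WT MEFs, 1 from NT and 1 from GS cells, and 4 chromatin segmentations built from H3K27me3 and mH2A1, named WT-NT, WT-GS, KO-NT and KO-GS. The series holds no SIRT7 ChIP from KO cells. Listed peaks that do not depend on SIRT7 could therefore not be recognised, in peak numbers or in their excess on X. Each list or segmentation pooled 2 replicates per ChIP target, so no value below has a replicate error, and the sequencing depth is unknown. The title of the series poses the question of how SIRT7 and macroH2A1.1 take part in the response to glucose starvation. The comparisons were therefore SIRT7 peaks between treatments, chromatin states between treatments and genotypes, and the states in which SIRT7 peaks lay.

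SIRT7 peaks were far more numerous in GS than in NT cells. The NT list held 90 peaks and the GS list 2671, or 29.7 GS peaks for each NT peak. On autosomes the numbers were 58 and 2272, and on chromosome X 32 and 396. Chromosome Y had 0 NT peaks and 3 GS peaks. The listed peaks covered 278 kb in NT and 4152 kb in GS, a ratio of 14.9. NT peaks on X were long, with a median of 6486 bp against 940.0 bp for NT peaks on autosomes (adjusted permutation p = 2e-05, from the smallest these permutations can give, 1e-05) and 1597 bp for GS peaks on X (adjusted permutation p = 2e-05). On autosomes the median was 1177 bp in GS, longer than the 940.0 bp in NT (adjusted permutation p = 0.0493, two-sided). With 1 list per treatment, and with the meaning of the score and the read totals unknown, the difference in number has no test. If the tag in the names of both lists is a cutoff on agreement between replicates, the number of listed peaks also depends on that agreement.

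Of the 90 NT peaks, 34 overlapped a GS peak (37.8%, Wilson 95% interval 28.5 to 48.1%), against a mean of 0.773 and a maximum of 7 when NT peaks were shifted along their chromosomes (one-sided permutation p = 0.0001, the smallest possible). Sharing was common on autosomes and rare on X. On autosomes 32 of 58 NT peaks overlapped a GS peak (55.2%, interval 42.5 to 67.3%), and on X 2 of 32 did (6.25%, interval 1.73 to 20.1%). The number on X was not distinguishable from shifted positions, with a mean of 0.631 (one-sided permutation p = 0.138). The shares on autosomes and X differed (odds ratio 18.5, two-sided Fisher's exact p = 2.62e-06). That test counts each peak as independent, whereas the 32 NT peaks on X fell into 9 clusters, so its p overstates the evidence. NT peaks on X lay nearer to GS peaks than shifted positions on X did, 25 of 32 within 100 kb against a shifted mean of 10.2 (permutation p = 0.0044), at a median distance of 33.5 kb against 224 kb (permutation p = 0.0018). Overlapping GS peaks numbered 34, or 1.27% of the GS list.

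The NT peaks with the highest scores were mostly also in the GS list. All 7 NT peaks with the highest score of 1000 overlapped a GS peak. They lay on chromosome 5 from 37051859 to 37052966, chromosome 3 from 95848277 to 95849111, chromosome 17 from 4626110 to 4626721 and from 56339160 to 56339617, chromosome 6 from 125826815 to 125827296 and from 132413590 to 132413978, and chromosome 1 from 45007912 to 45008202. The next 3 NT peaks by score lay on chromosome 9 from 19379796 to 19379997, on X from 120162364 to 120168965 and on chromosome 4 from 131301168 to 131302029, and only the last of these 3 did not overlap a GS peak. Of the 26 GS peaks with score 1000, 15 overlapped an NT peak. The 10 longest of these 26 included 4 on X, the longest spanning 17162 bp from 30700681 to 30717842, and the others starting at 145724964, 31915558 and 52182353. A further 5 lay on chromosome 4 between 145118642 and 146961804, of which 3 overlapped an NT peak, and 1 lay on chromosome 6 from 130527749 to 130530626.

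Chromosome X carried a higher density of SIRT7 peaks than the autosomes in both lists. In GS it held 2.38 peaks per Mb, 2.36 times the number its length predicts (adjusted permutation p = 0.0021), and in NT 0.192 peaks per Mb, 5.66 times its prediction (adjusted permutation p = 0.0042), both from the smallest permutation p possible, 0.0002. The 19 autosomes averaged 0.908 GS peaks per Mb (SD 0.159 over chromosomes), from 0.652 on chromosome 19 to 1.21 on chromosome 13. Besides chromosome Y, GS peaks were fewer than predicted on chromosomes 2, 5, 8, 9, 12, 16 and 19, but with peaks within 100 kb counted once only chromosomes 8 and Y stayed below (adjusted permutation p = 0.0266 for each). All GS peaks on Y started within its initial 3 Mb. The length of Y was not corrected for unassembled sequence, so its test cannot separate a lack of peaks from a lack of assembled sequence. When autosomes were compared among themselves only chromosome 13 passed the test, with 146 peaks, 1.32 times its prediction (adjusted permutation p = 0.0266). The peaks on X were clustered. A region from 22555994 to 30862144 held 80 GS peaks, 20.2% of those on X, and 18 of the 32 NT peaks on X lay in 2 clusters, from 144233884 to 146231006 with 10 NT and 10 GS peaks, and from 28266042 to 30939600 with 8 NT and 27 GS peaks. These clusters were chosen after their values were seen. With peaks over 5 kb left out, NT peaks on X were 1.96 times their prediction and no longer passed the test (adjusted permutation p = 1), since 24 of the 32 were that long.

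**Figure D1:**
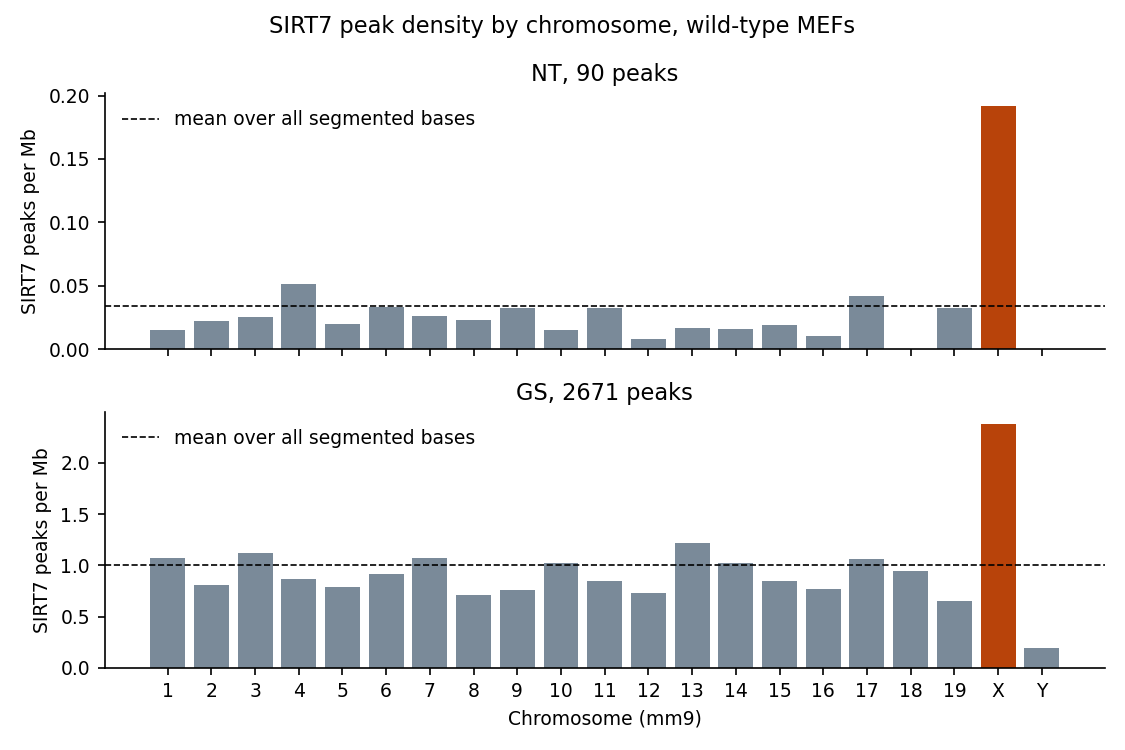
SIRT7 peaks per Mb on each chromosome (mm9) in NT (90 peaks) and GS (2671 peaks) WT cells, with the mean over all segmented bases as a dashed line. Chromosome X stands at 0.192 peaks per Mb in NT and 2.38 in GS, above each autosome, and the vertical scales differ between panels.

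The genome was divided among the chromatin states in similar proportions in NT and GS cells of each genotype, with a small shift in U4 that went opposite ways in WT and KO. U1 covered 70.5% of the genome in WT-NT and 70.1% in WT-GS, and 73.5% in KO-NT and 72.7% in KO-GS. U2 covered 19.6 and 19.8% in WT and 16.4 and 17.0% in KO, in the same order. In WT, U3 was higher in GS (8.42 against 7.88% of the genome, higher on 19 of 19 autosomes) and U4 lower (1.64 against 2.02%, lower on 19 of 19 autosomes). In KO, U4 was higher in GS (1.87 against 1.06%, a ratio of 1.77, higher on 19 of 19 autosomes and on X) and U3 lower (8.50 against 9.04%, lower on 12 of 19 autosomes). The U3 difference in KO rested on X, where U3 covered 20.9% in NT and 13.2% in GS. On autosomes alone GS minus NT for U3 was -0.0614 percentage points in KO and 0.708 in WT, and on X U3 was lower in GS in both genotypes. U4 shares depended on short segments, as the median U4 segment was a single bin of 200 bp. With bins merged into 1 kb, U4 covered 1.097% in WT-NT, 0.808% in WT-GS, 0.445% in KO-NT and 0.922% in KO-GS, and with segments under 1 kb joined to their neighbours 0.735, 0.496, 0.241 and 0.598%. GS minus NT for U4 kept its direction but shrank, from -0.382 percentage points to -0.289 and -0.239 in WT and from 0.815 to 0.478 and 0.357 in KO.

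The U4 bins that WT cells lost between NT and GS became U3 in 74.2% of cases and U2 in 21.4%, while the U3 bins that KO cells lost became U4 in 34.1% of cases, U2 in 34.0% and U1 in 31.9%. U4 segments were embedded in other marked sequence. In WT-NT, 56.9% of their borders were with U3, 41.0% with U2 and 2.15% with U1.

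**Figure D2:**
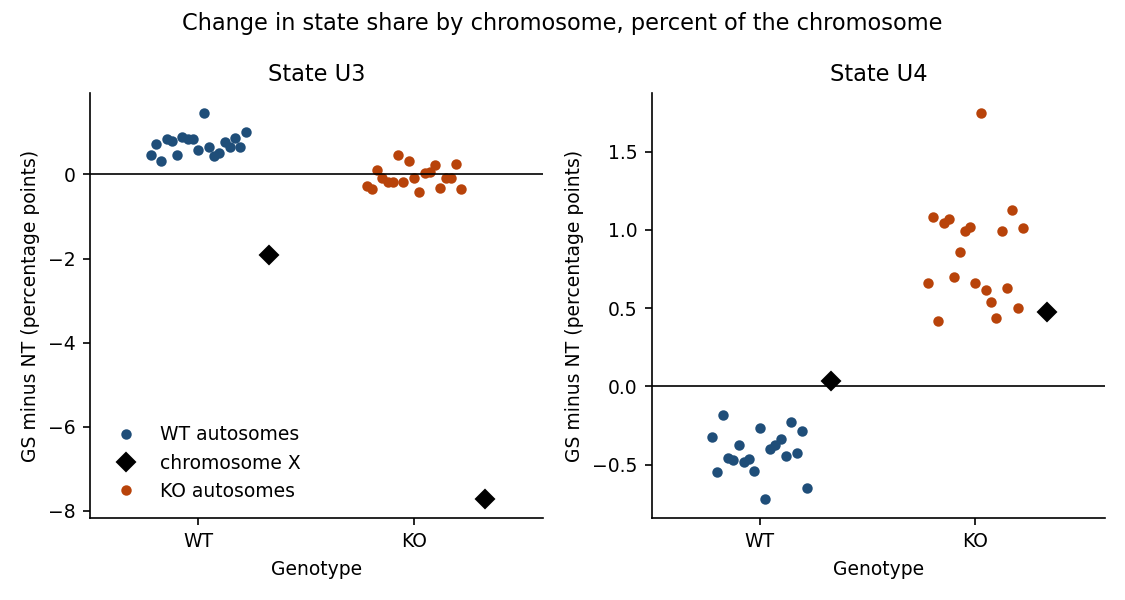
GS minus NT share of each chromosome in states U3 and U4, in percentage points, with 1 point per autosome (19) and a black diamond for X. U4 was lower on all 19 autosomes in WT and higher on all 19 in KO, and U3 on X was lower in both genotypes, while in WT it was higher on all 19 autosomes.

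The largest local shifts of WT and KO lay in different 1 Mb windows, except on chromosome 8, with no test attached to a single window. In WT, the window on chromosome 7 from 103000001 to 104000000 had the largest gain of U1 (36.4% in NT, 58.8% in GS) and the largest loss of U2 (46.0 to 20.04%), and the window on chromosome 13 from 27000001 to 28000000 had the largest gain of U2 (36.7 to 60.5%) and loss of U1 (63.3 to 39.5%). In KO the chromosome 7 window went the same way (U1 52.6 to 60.4%, U2 32.6 to 17.8%) and the chromosome 13 window the other way (U2 48.8 to 25.9%). For U3 in WT, the largest gain was on chromosome 8 from 123000001 to 124000000 (26.9 to 34.98%) and the largest loss on X from 48000001 to 49000000 (57.3 to 37.2%), where KO went the same way (73.3 to 40.2%). In KO the chromosome 8 window had the largest gain of U4 (8.68 to 25.3%), and its U3 share went from 43.5 to 29.6%. For U4 in WT the largest gain was on chromosome 16 from 30000001 to 31000000 (12.6 to 13.6%, a difference of 1.06 percentage points that was 0.200 with 1 kb bins and 2.10 with short segments joined) and the largest loss on chromosome 12 from 111000001 to 112000000 (17.4 to 11.8%). In KO the largest gain of U1 (24.7 to 63.1%), gain of U2 (22.2 to 43.4%), loss of U3 (61.3 to 22.4%) and loss of U4 (9.42 to 6.22%) all lay on X, in the windows starting at 82000001, 49000001, 74000001 and 73000001. With short segments joined the last of these differences was -0.880 percentage points in place of -3.20. The other KO windows lay on chromosome 7 from 151000001 (loss of U1, 58.1 to 29.9%) and from 38000001 (gain of U3, 31.7 to 40.1%), and on chromosome 2 from 141000001 (loss of U2, 72.1 to 48.4%).

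More of the genome changed state between NT and GS in KO than in WT cells. In WT 9.54% of bins (253 Mb) differed between treatments, and in KO 11.2% (296 Mb), with more change in KO on 20 of 20 chromosomes (1 to 19 and X). Chromosome X was 9.43% changed in WT and 17.6% in KO. Cohen's kappa between treatments was 0.793 in WT and 0.741 in KO. Change between treatments and imprecision of each segmentation cannot be separated without replicates, and the KO-NT segmentation enters the KO value alone.

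WT and KO cells differed in state at 11.4% of bins in NT (304 Mb) and 10.1% in GS (268 Mb). In KO the autosomes carried less marked sequence than in WT (26.5 against 30.6% in NT and 27.7 against 31.0% in GS). U2 was lower in KO on 19 of 19 autosomes in both treatments, by 3.15 percentage points over the genome in NT (SD over chromosomes 1.74) and 2.88 in GS (SD 1.67). In NT, U3 was higher in KO (9.04 against 7.88%, higher on 20 of 20 chromosomes, by 1.16 percentage points over the genome and 0.600 on autosomes) and U4 lower (1.06 against 2.02%, lower on 19 of 19 autosomes, KO minus WT -0.963 percentage points and -0.494 with short segments joined). In GS, U3 differed by 0.0761 percentage points over the genome, and on autosomes alone it was lower in KO. U4 was higher in KO in GS (1.87 against 1.64%, higher on 20 of 20 chromosomes), by 0.235 percentage points, or 0.147 on autosomes, 0.114 with 1 kb bins and 0.102 with short segments joined.

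Chromosome X went against the autosomes between genotypes. Its marked share was 15.8% in WT-NT and 16.3% in WT-GS, below the autosomes, and 30.03% in KO-NT and 24.7% in KO-GS. U3, which covered 11.4% of X in WT-NT and 9.48% in WT-GS, covered 20.9% in KO-NT and 13.2% in KO-GS. The autosome means of U3 were 7.72, 8.44, 8.32 and 8.26% in WT-NT, WT-GS, KO-NT and KO-GS, with SDs of 1.80, 2.01, 1.99 and 1.92. U2 was scarce on X in all 4 segmentations, from 3.67% in WT-NT to 9.11% in KO-GS, against autosome means of 17.3 to 21.03%. The U3 difference extended along the chromosome. Of 166 windows of 1 Mb on X, U3 was higher in KO in 123 and lower in 4 in NT, and higher in 119 and lower in 11 in GS. H3K27me3 and macroH2A1 are both known as features of the inactive X of female cells, and the sex of the cells is not given in the labels.

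**Figure D3:**
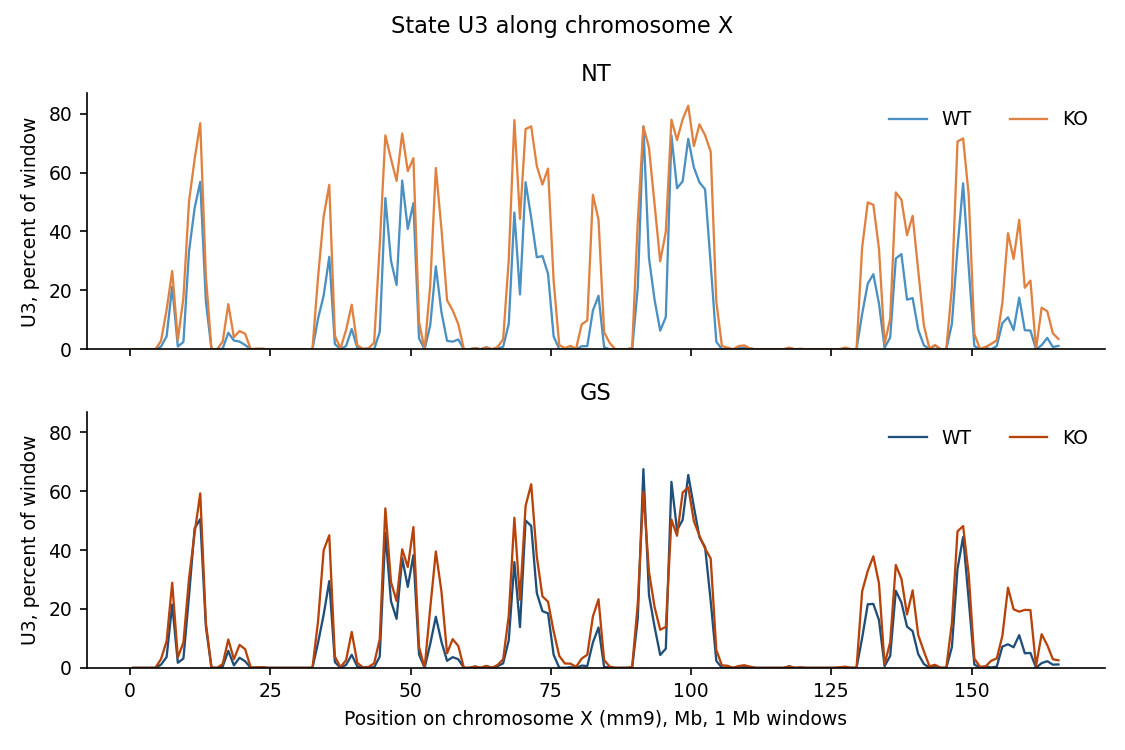
Share of state U3 in 1 Mb windows along chromosome X (mm9) in NT and GS cells, with 1 line per genotype and 166 windows. WT and KO lines rise in the same regions, and the KO line is higher in 123 windows in NT and 119 in GS.

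SIRT7 peaks lay mostly in U1, the state that covers most of the genome, and more often than their placement by chance gives. In the GS list 86.8% of peaks were U1 in WT-GS, the segmentation of the same genotype and treatment, against 71.4% of shifted peaks, and 11.2% were U2 (19.2% of shifted peaks), 1.98% U3 (8.68%) and 0 of 2671 U4 (0.787%), a count that allows a share of up to 0.112%. The pattern was the same in WT-NT, KO-NT and KO-GS, with 88.5, 86.5 and 89.3% of GS peaks in U1 against 71.8, 73.2 and 73.0% of shifted peaks. All 16 tests of the GS list passed with an adjusted permutation p of 0.0004, from the smallest possible p of 0.0002. The share of GS peaks in U3 was highest in KO-NT, at 5.62% (150 peaks) against 1.72% in WT-NT, 1.98% in WT-GS and 1.95% in KO-GS. All of the 10 GS peaks with the highest score and greatest length were U1 in all 4 segmentations. Of all GS peaks 2161 (80.9%) were U1 in all 4, a combination that covered 64.6% of the genome.

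NT peaks had similar shares, with 88.9% in U1 in WT-NT against 75.04% of shifted peaks (adjusted permutation p = 0.0107) and 1 of 90 in U3 against 9.49% (adjusted permutation p = 0.0171). In the NT list 7 tests passed: U3 in all 4 segmentations and U1 in all but KO-NT (85.6%, adjusted permutation p = 0.0608). No test of U2 or U4 passed in the NT list. Of the 10 NT peaks with the highest score, 8 were U1 in all 4 segmentations, the peak on chromosome 1 at 45007912 was U2 in all 4, and the peak on chromosome 6 at 125826815 was U1 in NT and U2 in GS in both genotypes. All 32 NT peaks on X were U1 in all 4. On autosomes alone the NT list no longer passed in WT-NT for U1 (82.8% of peaks, adjusted permutation p = 0.0768) or U3 (adjusted permutation p = 0.14), nor did it with the upper 50% of peaks by score (adjusted permutation p = 0.252 for U1 and 0.259 for U3).

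**Figure D4:**
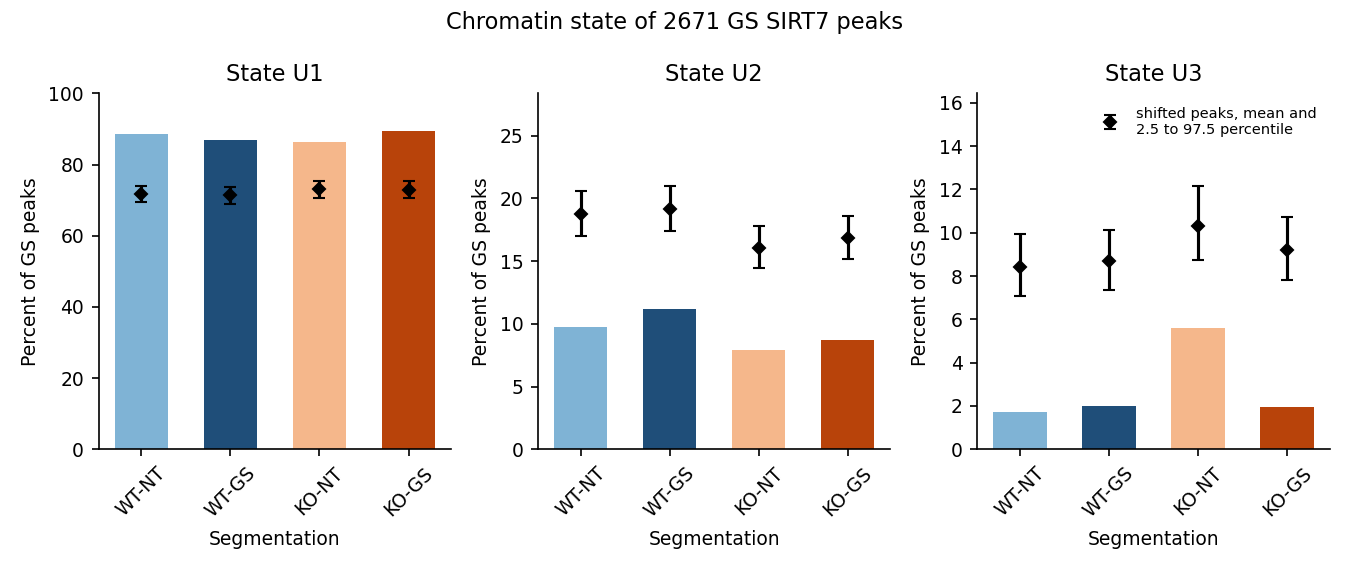
Percent of the 2671 GS SIRT7 peaks in states U1, U2 and U3 in each segmentation (bars), with the mean and the central 95% range of 10000 circular shifts (diamonds and lines). Bars lie above the shifted range for U1 and below it for U2 and U3 in all 4 segmentations.

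The share of GS peaks that changed state between NT and GS was not distinguishable from that of shifted peaks with the same starting states. In WT 158 of 2671 GS peaks changed (5.92%), against 6.48% of shifted peaks weighted to the NT states of the GS peaks, and in KO 251 changed (9.40%) against 8.65% (adjusted permutation p = 0.538 for both). All shifted peaks, without that weighting, changed more often (9.13% in WT, adjusted permutation p = 0.0012, from the smallest possible p of 0.0002, and 11.3% in KO, adjusted permutation p = 0.027), which goes with the excess of GS peaks in U1, the state that changed least. The most frequent changes in WT were U1 to U2 (83 peaks) and U2 to U1 (44 peaks). In KO they were U2 to U1 (73 peaks), U3 to U1 (70 peaks) and U1 to U2 (58 peaks). On autosomes alone the KO value was 9.20% against 10.4% of all shifted peaks and did not pass the test (adjusted permutation p = 0.19). The WT minus KO difference of -3.48 percentage points was not distinguishable from that of shifted peaks, -2.17, either without weighting (adjusted permutation p = 0.136) or with it (adjusted permutation p = 0.307). In the NT list 4 of 90 peaks changed in WT and 8 in KO, and neither passed the test (adjusted permutation p = 0.357 and 0.601).

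The sequence around GS peaks was also poor in marked states. The median distance from a GS peak to the nearest marked bin was 44.4 kb in WT-GS against 14.8 kb for shifted peaks, and 52.8, 54.4 and 50.2 kb in WT-NT, KO-NT and KO-GS against 16.3, 17.3 and 15.7 kb (permutation p = 0.002 in each, the smallest that 1000 shifts can give). Part of this follows from the excess of peaks in U1 itself. Among peaks in U1 the median was 70.6 kb in WT-GS against 45.4 kb for shifted peaks in U1, and 79.6, 86.2 and 70.8 kb in WT-NT, KO-NT and KO-GS against 48.9, 47.1 and 44.8 kb (permutation p = 0.002 in each).

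**Figure D5:**
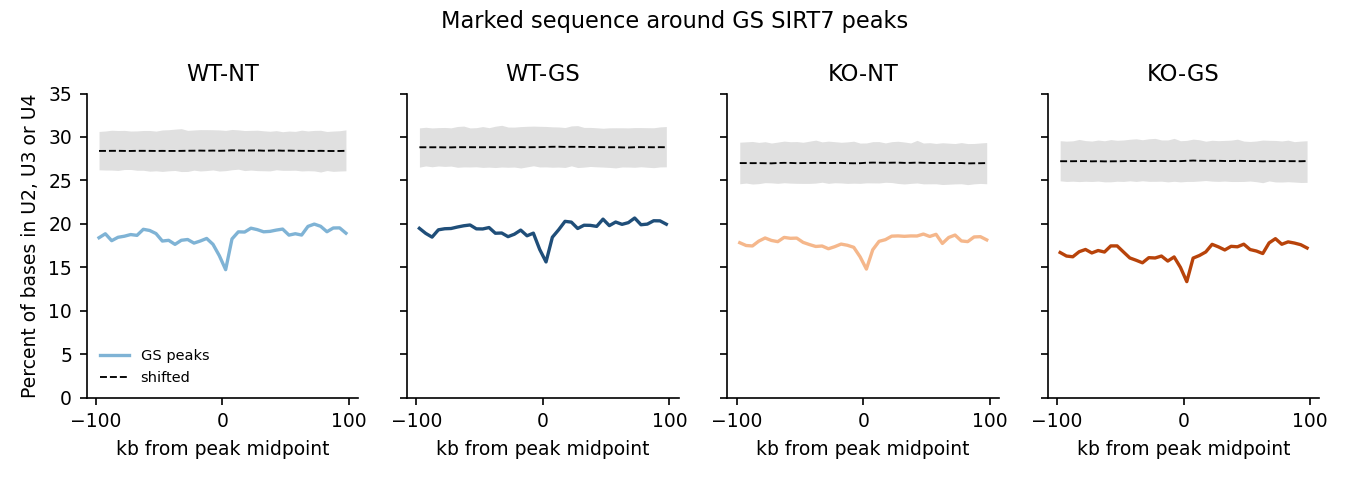
Percent of bases in U2, U3 or U4 in 5 kb steps within 100 kb of GS SIRT7 peak midpoints, for each segmentation (coloured lines), with the mean of 1000 circular shifts (dashed) and their central 95% range (grey). In WT-GS the share is 15.6% in the 5 kb after the midpoint, against 28.9% of shifted peaks, and stays below the shifted range out to 100 kb. The shifted peaks were not matched for state, so part of the gap follows from the excess of GS peaks in U1.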

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

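The tests in this part were chosen after the results were seen. U3 and U4 stood out because WT and KO moved in opposite directions between NT and GS: U3 by 0.540 percentage points of the genome in WT and by -0.541 in KO, and U4 by -0.382 in WT and by 0.815 in KO. For U3 the direction in KO rested on X: on autosomes alone the values were 0.708 in WT and -0.0614 in KO, and on X U3 was lower in GS in both genotypes. The difference between genotypes was not tested, since each segmentation is a single pooled file. A signal in sequence outside the main comparisons was also seen on chromosome Y, where 68.0 kb were marked in WT-NT and 75.2 kb in WT-GS and 0 kb in both KO segmentations, and on the mitochondrial chromosome, where 5.0 of 16.2 kb were marked in KO-NT and 0 kb in the other 3 segmentations.

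Chromosomes X and Y moved together between genotypes, with more marked sequence on X and none on Y in KO. Fewer bases called as marked throughout the KO genome cannot alone account for this, because X was the exception: its marked share was at least 8.42 percentage points higher in KO in both treatments while all 19 autosomes were lower. That follows from the pattern itself and is not a separate test. A different sex composition of the cultures is a candidate explanation, as more female cells in KO could add inactive X chromatin and remove Y. It was not tested: X had less U1 in KO in at least 128 of 166 windows in each treatment, which restates the pattern. An effect of the loss of SIRT7 in cells of the same sex cannot be told apart from it, because the marked 68.0 kb of Y in WT-NT were absent from both KO segmentations and the labels give no sex. Every WT to KO difference on X therefore stays open.

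For the opposite shifts of U4, lower detection of both marks in WT-GS cannot be the whole account of the WT part, because marked sequence increased from WT-NT to WT-GS on 16 of 19 autosomes. In KO, higher detection of both marks in KO-GS than in KO-NT cannot alone account for the values on X, where U4 was higher in GS. There the marked share changed by -5.33 percentage points and U1 was higher in GS in 107 of 166 windows and lower in 26. Higher detection together with another difference on X stays open, as the sex composition of each culture is unknown. On autosomes, where marked sequence increased on 18 of 19, by 1.21 percentage points, higher detection cannot be told apart from a gain of the marks, and X going the other way counts against 1 cause acting alone on all chromosomes. Lower detection in WT-GS of only the mark that sets U4 apart from U3 cannot be told apart from a loss of that mark, as U2 increased on 10 of 19 autosomes and which mark each state holds is not known. A biological response of the marks to treatment that differs between genotypes also stays open and untested. Whether U4 was defined alike in each segmentation is unknown, which limits every comparison of its share.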

How the results depend on the processing

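The alternatives with peaks over 5 kb left out, with autosomes or X alone in the overlap test and with shifted peaks weighted to the NT states were chosen after the results were seen, and the others before the data were examined. Of 521 alternative values, 463 were counted as unchanged. Tested values had to keep their side of the threshold, and their direction only if either value passed. Values without a test had to move by less than 1 SD over chromosomes, or by at most 1.5 times for counts. Differences without a test also had to keep their sign. That SD is spread along the genome and not replicate error, so the measure is lenient. In KO, GS minus NT for U3 was -0.541 percentage points over the genome and -0.0614 on autosomes. It counted as unchanged, as the SD was 1.73. All 16 state results of the GS list were unchanged in this sense under their 6 alternatives. So were the shares of the genome that changed state under their 5, which include state matching. Among the others, 18 values for named windows and 10 for genome shares moved by more than 1 SD without a change of sign. Matching states by shared bases moved 0 state numbers and so tested nothing.

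With the upper 50% of each list by score there were 45 NT and 1336 GS peaks, which follows from the filter, and on autosomes 58 NT peaks. Overlap on X alone was 6.25% (permutation p = 0.138). Without peaks over 5 kb, the NT ratio on X was 1.96 and 0 chromosomes were above expectation in NT, while in GS 2 were, as with the initial 3 Mb left out. Counting peaks within 100 kb once left 2 of 8 chromosomes below expectation in GS, chromosomes 8 and Y. On autosomes alone the GS difference in U3 between WT and KO was -0.169 percentage points, reversed because X carried the positive value. The U4 gain in KO was 0.478 with 1 kb bins and 0.357 with segments under 1 kb joined, and with 1 kb bins X minus autosomes for U4 was 0.175 in KO-NT and reversed to -0.100 in KO-GS, as short U4 segments were removed. In the NT list, U1 in KO-NT (85.6%) came to pass with uniform placement (adjusted permutation p = 0.00669) and without the initial 3 Mb (0.0472). With the upper 50% by score U1 was 84.4% in WT-NT, WT-GS and KO-GS, and U3 2.22% in WT-NT and KO-NT and 0% in WT-GS. On autosomes U1 was 82.8% in WT-NT and 79.3% in WT-GS and KO-GS, and U3 1.72% in WT-NT, WT-GS and KO-GS and 3.45% in KO-NT. None of these 13 passed, with fewer peaks tested. State change at GS peaks in KO was 9.20% on autosomes and did not pass; the cause was not tested. Against shifted peaks weighted to the NT states, WT (5.92%, shifted 6.48%) no longer passed and KO (9.40%, shifted 8.65%) reversed without passing, as U1 bins changed least.

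No paired analysis was possible because the files pool the replicates numbered 1 and 2, and leaving out a replicate was not run for the same reason. Promoter and feature alternatives were not run without an mm9 annotation. Unknown depth limits all comparisons of peak number and marked share.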

Other observations

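The tests of U3 at GS peaks by treatment and of KO-NT minus WT-NT were chosen only after the result was seen, and those of U3 found in KO-NT alone were set before it. The test of marked sequence away from the peaks was set before its own values were seen, but after the profile around all peaks was. GS peaks on X and on autosomes differed in how often they were U3 in KO-NT: 45 of 396 peaks on X (11.4%) and 105 of 2272 on autosomes (4.62%), against 9 and 37 in WT-NT. In KO-GS the numbers were 11 and 41. U3 also covered more of X (20.9%) than of the autosomes (mean 8.32%) in KO-NT.

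More U3 across KO-NT cannot account for the larger number of autosomal GS peaks in U3 in KO-NT than in WT-NT. On X the difference test cannot decide this. U3 stayed rarer at GS peaks than at shifted positions: in KO-NT 105 against 189.6 on autosomes and 45 against 86.1 on X. In WT-NT the numbers were 37 against 179.3 and 9 against 45.7. KO-NT minus WT-NT was 68 peaks on autosomes against a mean of 10.4 in shifts (permutation p = 0.0002, the smallest possible), and 31 autosomal peaks were U3 in KO-NT and U1 in the other 3 segmentations against 2.65 (adjusted permutation p = 0.00799 over 4 segmentations, from the smallest that 1000 shifts can give, 0.002), while on X it was 36 against 40.4 (permutation p = 0.683). The difference test compares numbers and not ratios to the shifted number. On X the rise from 9 to 45 GS peaks was proportionally larger than that from 45.7 to 86.1 at shifted positions. Whether more U3 across X accounts for it, and whether X and autosomes differ, is therefore open. The values of KO-GS cells, which also lack SIRT7, argue against its absence whatever the treatment as the whole account. They had 1.95% of GS peaks in U3, within the interval of WT-GS (1.52 to 2.59%). That interval covers counting error only, and with 1 pooled segmentation per condition the explanation is not excluded. Background calls in KO-NT stay open: KO-NT was also the only segmentation with marked mitochondrial sequence (5.0 of 16.2 kb), and its U3 segments at these peaks had a median of 2200 bp against 600 bp elsewhere, within the 400.0 to 3203 bp of shifted peaks (central 95% range, permutation p = 0.288). An effect of SIRT7 loss in NT cells alone is open and untested; of all GS peaks, whatever their state, 34 of 2671 overlapped an NT peak.

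GS peaks lay in stretches poorer in marked sequence than the excess in U1 alone gives. If peaks avoided marked sequence only where they sit, peaks in U1 would have the same share marked 50 to 100 kb away as shifted peaks in U1. It was 14.1% in WT-GS against 18.1%, and below the central 95% range of the shifts in all 4 segmentations (permutation p = 0.002 in each, the smallest that 1000 shifts can give). KO cells, which lack SIRT7, had 12.5% in both treatments, against 16.7% for shifted peaks in U1 in KO-NT and 17.1% in KO-GS. Unassembled sequence is also U1, but it holds no peaks. It therefore lowers the marked share near shifted peaks in U1 and works against this difference. Assembled stretches that are all U1 can hold peaks and could work the other way. The cluster on X from 28266042 to 30939600, with 8 NT and 27 GS peaks, lay in windows wholly U1 in all 4 segmentations. Whether such stretches lack the marks or only lack signal was not tested, so their part in this difference is open.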
